A study of Mus musculus with 2 samples.

How the data were processed

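Pancreatic tumours of KPPC mice were profiled by droplet single-cell RNA sequencing, with 1 library named control and 1 named RMC-6236 in the sample titles. Per the labels' design text, the comparison arm received DMSO. The labels disagree on other points. Their treatment field describes Ulixertinib, an ERK inhibitor, at 100 mg/kg by mouth daily for 14 days with 4 mice per group, and their treatment tag has the same entry for both samples. The dose and duration of RMC-6236 are therefore not stated here, and it is not known whether a library pools several mice. The extraction text mixes 5′ gene expression with nuclei isolation, so whether cells or nuclei were loaded is not settled. The growth text says KPC, while the titles say KPPC and the genotype field gives conditional deletion of Trp53 on both copies, which is followed here. Barcodes are called cells throughout.

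Each deposited matrix holds raw UMI counts per gene and barcode, which the authors made with Cell Ranger 8.0.1, per the file headers. The counts were whole numbers and had not been normalised. The submitters' processing notes name bcl2fastq, STAR 2.5.1a, Subread, featureCounts 1.4.6-p5 and edgeR together with a human genome build. Their role for these mouse matrices, and the mouse build and annotation, are not given in the sources used here. Genes are therefore given by the symbols and Ensembl identifiers of the files, without coordinates.

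The control library had 12602 barcodes with 48842278 UMIs and the RMC-6236 library 11103 barcodes with 40578830 UMIs. The lowest barcode in each held 500 UMIs, so the matrices were already restricted to barcodes above a minimum. Barcodes with at least 200 genes, at least 500 UMIs and at most 20.0% mitochondrial UMIs were kept. This filter removed 1388 barcodes (11.0%) of the control library and 2954 (26.6%) of the RMC-6236 library. Doublets were called per library with Scrublet in scanpy, at its automatic score threshold. It removed 267 of 11214 control cells (2.38%, threshold 0.223) and 0 of 8149 RMC-6236 cells (threshold 0.611). In the RMC-6236 library the automatic threshold had not worked, so doublets remain there. An alternative applied the control threshold to both libraries and removed 118 RMC-6236 cells (1.45%). The kept set was 10947 control and 8149 RMC-6236 cells.

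Counts were scaled to 10000 per cell, log-transformed and reduced to 2000 variable genes and 30 principal components. Cells of both libraries were clustered together, without batch correction, on a shared-neighbour graph of 15 neighbours with the Leiden algorithm at resolution 1.0. A cluster took the name of the marker class, out of 18 fixed classes, with the largest share of markers at least 2-fold above the other clusters and detected in at least 10% of its cells. At least 3 such markers were required. Clusters led by interferon or cell cycle genes more than by markers stayed unnamed, as did shallow clusters without a marker among their 10 leading genes. Of the 24 clusters, 2 stayed unnamed, with 201 of 10947 control cells (1.84%) and 136 of 8149 RMC-6236 cells (1.67%). The interferon-led cluster 12, closest to B cells, held 123 (1.12%) and 12 (0.15%) of these, and the cycling cluster 22, closest to plasma cells, 78 (0.71%) and 124 (1.52%). Interferon genes that lead cluster 12 differ between the libraries, so no difference in cell types is read from its size. A class was compared as a whole only if none of its clusters had more markers of another class than of its own among its 10 leading genes. Fibroblasts failed this rule and were compared as clusters 19 and 20, and their pooled share is given only in a plot and among the alternatives. Classes with under 100 cells in either library were not compared for gene expression.

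UMIs were summed per library and class, and divided by the total UMIs of that sum to give CPM. A log2 ratio is RMC-6236 over control with 0.5 counts added to each sum. With 1 library per group there are no replicates, so no test was made and no p-value is given. Intervals are at the 95% level: Clopper-Pearson for shares, exact Poisson for sums, and exact conditional binomial for ratios. They cover counting error only, not the spread between animals or preparations. Those of UMI sums and UMI ratios, and the list ranges below, take each UMI as independent. They leave out the spread between cells, and are too narrow where few cells hold most UMIs of a gene. Where a gene had 0 UMIs in 1 library, its fold is a lower bound against a floor of 3 counts in that library's class sum, and where no cell had a UMI, the share allowed is 3 cells of the total. For gene lists, members with at least 20 UMIs over both libraries were measured. A list is summarised by the median log2 ratio of its measured members, with a range from 1000 Poisson redraws of their counts. Its percentile is taken among 10000 random lists of the same size drawn from 20 bins of mean expression, and is a description of these libraries. The 36 lists came from general knowledge of the pathways and cell types, and lists share some members. Shares of cells with a UMI were compared after each cell was thinned to 1000 UMIs, leaving shallower cells out.

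The genes named in the epithelial class follow a rule: the 13 highest and 13 lowest log2 ratios among genes with at least 50 UMIs in the higher library and a mean of at least 50 CPM. Mitochondrial, ribosomal, haemoglobin, antigen receptor, Y-linked and unnamed genes and Xist were left out. So was any gene whose CPM in the class was under 10% of its CPM in another class of the same library with at least 50 cells. In other classes the rule takes 5 genes on each side. For each list, up to 4 members with the highest and lowest ratios may be named. The genes of the thinned shares, Kras and Trp53 are always given. This rule, the groups, the marker classes and the main settings were chosen before the data were examined.

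The alternatives planned at that time were no cell filter, a stricter filter (500 genes, 1000 UMIs, 10% mitochondrial), Scrublet calls kept, Leiden resolutions of 0.5 and 2.0, 4000 variable genes and each library clustered alone. Others were scaling by TMM (edgeR) or by the median of ratios (DESeq2), 5 counts added, no minimum for list members, the mean of each cell's CPM, thinned cells, and subtraction of 10% of the UMIs in proportion to the library's mean profile. With only 2 columns, size factors from the median of ratios are coarse. Alternatives added after seeing the data were the common Scrublet threshold, the deep epithelial cluster alone, that cluster without its mesenchymal sub-cluster, and leaving out the 2 cells with the most UMIs of a gene or the 10 with the most of a list. Sub-clusters were found at resolution 0.3 by the same steps.

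The ratio and list computations were tested on simulated data drawn from the epithelial class sums (13730 genes, 50 changed genes per fold). Medians of 1.99, 0.98, -0.98 and -1.99 were recovered for true folds of 4.0, 2.0, 0.5 and 0.25, and the intervals held the true value for 88.0% to 96.0% of genes. Of 100 lists of 30 unchanged genes, 6.0% fell outside the 5th to 95th percentile. The simulated counts were independent Poisson draws, which is what the intervals assume. The test therefore checks the computation, not how well the intervals hold where few cells carry most UMIs of a gene. The work used Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0. No genome reference was used here.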

Results

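Tumours of KPPC mice, whose pancreatic cells, by the genotype label, carry an activated Kras allele and lack Trp53, were compared with and without RMC-6236 (daraxonrasib), an inhibitor of the active, GTP-bound form of mutant and normal RAS proteins. The series title asks how blocking this pathway bears on interferon signalling and on the mesenchymal state of tumour cells. The measurement was the number of UMIs, each standing for 1 captured mRNA molecule, per gene and cell. The control library gave 10947 cells with 45935986 UMIs and a median of 3071 UMIs per cell. The RMC-6236 library gave 8149 cells with 37547145 UMIs and a median of 2827. Each group was 1 library, so differences below are differences between these libraries and have no replicate check. The filter removed 26.6% of RMC-6236 barcodes and 11.01% of control barcodes, and the median mitochondrial share before filtering was 4.43% against 3.27%.

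Epithelial cells and both clusters named fibroblast made up larger shares of the RMC-6236 library, and T and B cells smaller ones. Epithelial cells, which here include ductal and tumour cells, were 4.99% (4.59 to 5.41) of control cells and 11.4% (10.7 to 12.1) of RMC-6236 cells, a 2.29-fold difference (2.05 to 2.55). Of these, 400 control and 664 RMC-6236 cells lay in the shallow cluster 5 (median 850 and 886 UMIs), named on 8 of 19 markers. The deeper cluster 18 held 146 and 265 cells and was named on 19 of 19. Fibroblast cluster 19 was 1.41% (1.19 to 1.65) and 5.06% (4.59 to 5.55), 3.59-fold higher (2.98 to 4.35), and cluster 20 1.04% (0.86 to 1.25) and 3.75% (3.35 to 4.19), 3.61-fold higher (2.90 to 4.51). The pair is not compared as a class, because the 10 leading genes of cluster 19 held no fibroblast marker and 1 of another class. T cells were 29.7% (28.9 to 30.6) and 20.7% (19.8 to 21.5), 1.44-fold lower (1.36 to 1.53), and B cells 33.1% (32.2 to 34.0) and 26.8% (25.9 to 27.8), a log2 ratio of -0.30. Macrophages were 1.21-fold higher (1.12 to 1.30), at 13.9% and 16.8%, and the digestive-enzyme-producing acinar cells 1.96-fold higher (1.65 to 2.34), at 2.02% and 3.96%. Neutrophils took 4.52% and 3.46%, dendritic cells 2.94% and 3.47%, natural killer cells 1.29% and 1.59%, and endothelial cells 0.78% and 1.29%. Erythroid cells, the red blood cell lineage, numbered 262 in the control and 2 in the RMC-6236 library, a log2 ratio of -6.61 (-9.66 to -4.74).

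Within T cells, the cluster led by Cd4 and Cd40lg was 12.9% of control and 7.28% of RMC-6236 cells, and that led by Cd8b1 and Cd8a 8.86% and 5.02%, each 1.77-fold lower. The cluster led by Foxp3, the regulatory T cell factor, took 4.30% and 4.34%. Within B cells, cluster 0 was 27.1% and 19.6% and cluster 10 3.70% and 3.02%, whereas cluster 7, led by Spib and Blk among others, was 2.28% and 4.23%, 1.85-fold higher (1.57 to 2.19). Acinar was the second-closest class of cluster 7, with a share of 0.615 of acinar markers raised by the naming rule. Scrublet removed 0 RMC-6236 cells, so cluster 7 is not read as a B cell subset of larger size. Shares add up to a whole and depend on how tissue was dissociated and filtered. When each library was clustered alone, the epithelial log2 ratio moved from 1.19 to 0.25, the acinar one from 0.97 to 1.56 and the macrophage one from 0.27 to -0.02, and with every barcode kept the erythroid one moved to -3.69. Mmp7 and Cldn4, among the 10 leading genes of the deeper epithelial cluster, themselves differed between the libraries.

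**Figure D1:**
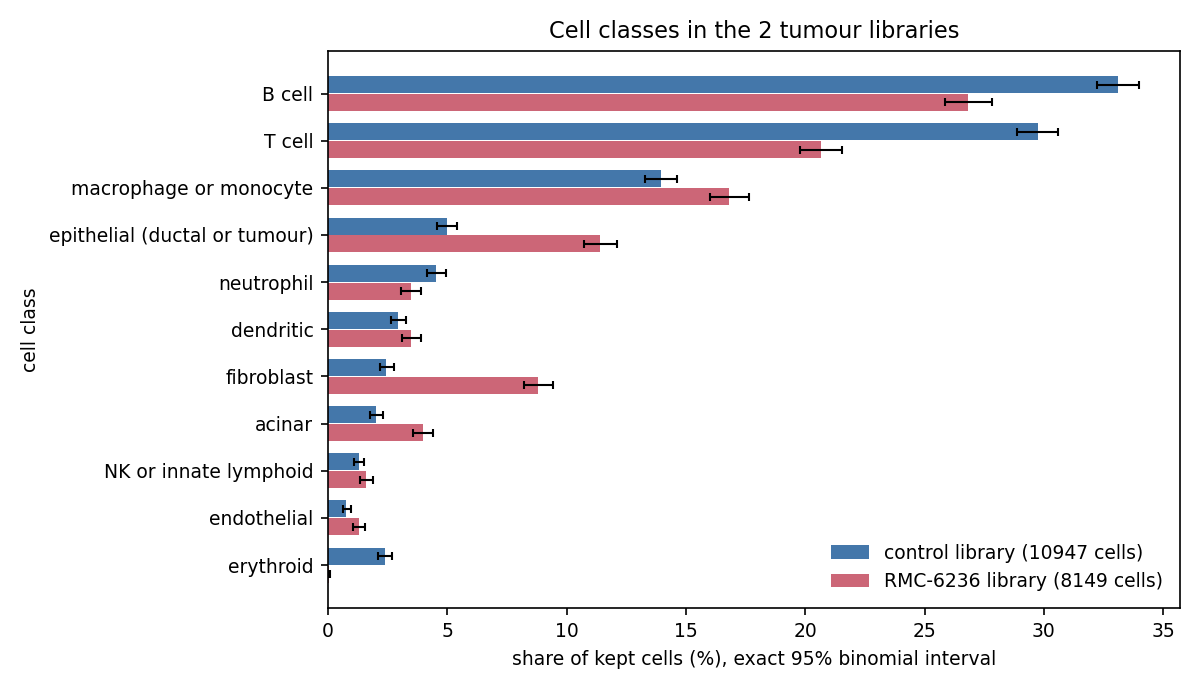
Share of kept cells in each named class, in percent, for the control and the RMC-6236 library, with exact 95% binomial intervals as bars. Epithelial cells stand at 4.99% and 11.4% and T cells at 29.7% and 20.7%, and the fibroblast bars (2.45% and 8.81%) pool clusters 19 and 20, which were otherwise compared apart.

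Genes of the type I interferon response, which are switched on by interferon alpha and beta, were lower in the epithelial cells of the RMC-6236 library. All 38 measured members had lower values, 25 of them at least 2-fold, with a median log2 ratio of -1.39 (-1.62 to -1.15) at percentile 0.00 of the random lists. Isg15 (ENSMUSG00000035692), a ubiquitin-like modifier, stood at 102 CPM in control and 15.9 CPM in RMC-6236 cells, 6.36-fold lower (log2 ratio -2.67, -2.97 to -2.38). Bst2 (ENSMUSG00000046718), a surface protein that tethers virus particles, was 173 and 37.7 CPM (-2.19, -2.39 to -2.00). Ifit3 (ENSMUSG00000074896), an RNA-response gene induced by interferon, was 19.5 and 1.56 CPM (-3.59, -4.65 to -2.77), and the deubiquitinase Usp18, a brake on interferon receptor signalling, 22.4 and 1.69 CPM (-3.68, -4.69 to -2.90). Ifit3b had the lowest member ratio (-4.44) and came from 10 control cells. The highest ratios included that of Samd9l, at -0.28 (-0.57 to 0.02).

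MHC class I presentation genes were also lower, in 17 of 18 members, with a median of -0.36 (-0.45 to -0.23, percentile 0.01). Within the sub-clusters of the deeper epithelial cluster this median was 0.006 (-0.175 to 0.164) and -0.34 (-0.51 to -0.22). In the mesenchymal sub-cluster, with 14 control cells, it was -2.01 (-2.45 to -1.605). B2m, the shared light chain of class I molecules, was 433 and 261 CPM (-0.73, -0.82 to -0.64), and the heavy chain gene H2-K1 276 and 215 CPM (-0.36), or 0.14 as a mean of cells' CPM. MHC class II genes had a median of -0.28 (-0.40 to -0.16, percentile 0.88, 9 of 11 lower), and H2-Aa was 109 and 83.0 CPM, beside dendritic cell markers of 146 and 84.9 CPM in the class. The class II median turned to 0.45 in thinned cells and to 0.48 without the 10 cells of each library with the most UMIs of the list, and H2-Aa to 0.03 without its 2 top cells. Interferon gamma response genes had a median of -0.21 (-0.53 to 0.02, percentile 1.19, 14 of 21 lower), with Ifi47 at -1.60 (-2.77 to -0.56). That median was 0.03 after subtraction of free RNA and 1.70 over the 3 members measured in thinned cells. Interferon ligands and receptors had a median of 0.04 over 5 members (percentile 54.4), and cytosolic nucleic acid sensors -0.25 (percentile 0.37, 8 of 12 lower), or 0.40 over 4 members in thinned cells.

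Part of the type I interferon difference lay in few cells and in cells of a mesenchymal sub-cluster. Isg15 was detected in 60 of 546 control and 33 of 929 RMC-6236 cells, and Ifit3 in 13 and 9. The list median was -0.32 over the 8 members that could be measured in thinned cells. At resolution 2.0 Isg15 was -1.29, Bst2 -1.20 and Ifit3 -2.52, and Ifit3 was -1.70 in thinned cells. In the deeper epithelial cluster alone the median was -1.51, Isg15 -2.73, Bst2 -2.31, Ifit3 -3.83 and Samd9l -0.33. Without its mesenchymal sub-cluster the median was -0.98, Isg15 -1.02, Bst2 -1.16, Ifit3 -2.24 and Samd9l 0.07. Markers of T cells (124 and 128 CPM) and of B cells (172 and 164 CPM) were close in the epithelial cells of both libraries.

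Genes that report RAS-MAPK output, the pathway that the inhibitor blocks, were lower by a small amount in RMC-6236 epithelial cells. Their median was -0.16 (-0.23 to -0.07, percentile 0.38), 17 of 26 members were lower, none by 2-fold, and summed CPM was 4479 and 3851. The median was -0.13 in the deeper epithelial cluster alone and -0.23 there without its mesenchymal sub-cluster, but within its 3 sub-clusters the interval held 0 each time, at 0.03 (-0.10 to 0.12), -0.04 (-0.15 to 0.15) and -0.04 (-0.24 to 0.04). Among the lower members, the stress-response gene Ier3 was 494 and 322 CPM (-0.62, -0.70 to -0.54) and the transcription factor Egr1 661 and 476 CPM (-0.47, -0.54 to -0.40), although Egr1 stood at 0.001 in thinned cells. Egr1 is also on the list of immediate early and dissociation-stress genes, whose median was lower, at -0.40. Etv1, a transcription factor, was higher at 9.63 and 27.4 CPM (1.5, 1.04 to 2.0), and Spry1, a feedback inhibitor of the pathway, 11.9 and 18.8 CPM (0.65, 0.20 to 1.13; 0.04 in thinned cells). The ERK phosphatase Dusp6 was 74.9 and 85.9 CPM (0.20, 0.01 to 0.39), a direction that turned in thinned cells (-0.11) and in the mean of cells' CPM (-0.06). Spry4 was 14.4 and 13.4 CPM (-0.12, -0.57 to 0.35). Kras itself (ENSMUSG00000030265) was 196 and 182 CPM (-0.10, -0.22 to 0.02), counted over all its alleles, and Trp53 22.2 and 30.3 CPM (0.45, 0.12 to 0.80). Counts per gene do not show whether the Trp53 UMIs lie outside the deleted part, so they do not check the deletion.

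Epithelial identity genes stood at close to the same level in the class sums of both libraries. Their median was 0.01 (-0.03 to 0.08, percentile 59.4), with 16 of 31 higher, and -0.03 under either other scaling. Within the sub-clusters of the deeper epithelial cluster it was 0.23 (0.12 to 0.30), -0.05 (-0.10 to 0.01) and, over 9 members in the mesenchymal one, 1.285 (0.75 to 1.62). The adhesion molecule Epcam was 1079 and 1075 CPM and the ductal keratin Krt19 1069 and 1189 CPM (0.15, 0.10 to 0.20). The tight-junction gene Cldn4 was lower, at 376 and 254 CPM (-0.57), and the surface glycoprotein Tacstd2 higher, at 11.1 and 18.5 CPM (0.73, 0.28 to 1.22).

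Genes of the mesenchymal transition, in which epithelial cells take on fibroblast-like features, were higher for most members in RMC-6236 epithelial cells. The median was 0.66 (0.51 to 0.90, percentile 100), with 26 of 35 higher and 13 at least 2-fold, while summed CPM went the other way, 5092 and 4725. Col1a2 (ENSMUSG00000029661), a fibrillar collagen chain, was 6.70 and 134 CPM, 19.7-fold higher (4.30, 3.81 to 4.88), and was detected in 23 and 154 cells. It was 2.08 as a mean of cells' CPM and 2.60 at resolution 2.0. Tnc (ENSMUSG00000028364), a matrix glycoprotein, was lower at 434 and 92.9 CPM (-2.22, -2.35 to -2.10), with 59.6% of its control UMIs in 2 cells, and the surface nucleotidase Nt5e 83.3 and 42.0 CPM (-0.99). Vimentin (Vim) was 937 and 907 CPM (-0.05, -0.10 to 0.01) and the transcription factor Zeb1 65.7 and 80.0 CPM (0.28, 0.09 to 0.48). Fibroblast markers in the class stood at 103 and 590 CPM beside these values, a sum that includes list members such as Col1a2. The 7 markers outside the list stood at 17.2 and 56.0 CPM in the deeper cluster and at 69.4 and 105.7 CPM in the shallow one. In the deeper epithelial cluster alone, leaving out the shallow one, the list median was 0.745, Col1a2 7.30, Vim 0.03 and Zeb1 0.30. Without its mesenchymal sub-cluster as well, these were -0.07, 2.998, -1.47 and -0.52, with Col1a2 on only 3 and 2 control UMIs, and Zeb1 was also negative at Leiden resolution 2.0 (-0.02).

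Receptor tyrosine kinases and their ligands had a median of 0.35 (0.17 to 0.47, percentile 99.9, 15 of 20 higher), with summed CPM of 1090 and 1053. The fibroblast-type receptor Pdgfra rested on 4 and 58 UMIs (3.01, 1.73 to 5.09), while the epidermal growth factor receptor Egfr was lower at 184 and 115 CPM (-0.67, -0.81 to -0.54). In the deeper cluster alone this median was 0.22 and Pdgfra 3.23, and -0.02 and 0.38 without its mesenchymal sub-cluster, with 3 control UMIs of Pdgfra both times. TGF-beta response genes (-0.02, percentile 32.1) and YAP-TEAD targets (-0.12, percentile 4.33, 14 of 19 lower) were near 0.

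Among the 13 genes with the highest ratios in epithelial cells, the matrix protease Mmp7 (ENSMUSG00000018623) was 163 and 920 CPM, 5.63-fold higher (2.49, 2.39 to 2.60), in 59 and 212 cells. Over both libraries Mmp7 was 1510 CPM in the deeper cluster's sub-cluster led by Tff1 and Tff2 among others, against 244 and 59.0 CPM in the other sub-clusters. The part of the mix of sub-clusters in the Mmp7 ratio was not tested. The iron-binding protein Lcn2 was 239 and 803 CPM (1.75, 1.66 to 1.84) in 42 and 196 cells, the aldo-keto reductase Akr1b7 37.3 and 146 CPM (1.97), the kinase Camk2b 84.3 and 314 CPM (1.89) and the glutathione transferase Gsta3 26.6 and 96.5 CPM (1.86). The proteoglycan Bgn was 18.8 and 234 CPM (3.63, 3.33 to 3.96; 2.07 as a mean of cells' CPM) and the transcriptional repressor Id3 25.5 and 113 CPM (2.15, 1.88 to 2.44; 0.87 at resolution 2.0), or 3.76 and 2.13 in the deeper cluster alone and 1.07 and 0.52 there without its mesenchymal sub-cluster. The islet hormone genes Ppy, Iapp, Gcg, Ins2 and Ins1 led the ranking (9.21, 9.15, 7.57, 6.96 and 6.61), and 2 RMC-6236 cells held 99.2% of that library's 9496 hormone UMIs. Without the 2 top cells of each library for a gene, Ins1 stood at 0.37 and Ins2 at -0.40, Ppy had 45 RMC-6236 UMIs against 0 and Iapp 6 against 0, and no Gcg UMI was left in either library. Spink4 (2.64) rested on 2 cells in the same way, and was 0.22 without them.

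Among the 13 lowest, apart from Isg15, Bst2 and Tnc, were the cell cycle kinase Cdk6 at 477 and 190 CPM (-1.33, -1.43 to -1.23), the protease Adam12 at 122 and 36.8 CPM (-1.73, -1.94 to -1.53), Ccbe1 at 166 and 51.6 CPM (-1.68), the metalloreductase Steap2 at 103 and 39.8 CPM (-1.37) and Gatad1 at 223 and 89.8 CPM (-1.31). The gastric-type genes Gkn2 (-8.09), Clca1 (-6.52), Gkn1 (-5.82), Psca (-4.77) and Tff1 (-2.10) were also in this group. In the control library 2 cells held most of the UMIs of each gene, from 90.8% for Tff1 to 99.3% for Gkn2, and without the 2 top cells of each library Psca stood at 0.13, Tff1 at 0.42, Gkn2 at -2.02 and Gkn1 at -1.87. Clca1, with UMIs in only 4 and 3 cells, was then 51 UMIs against 1 (-5.83), and -2.35 as a mean of cells' CPM and -2.54 in thinned cells. Over both libraries Adam12 was 161 CPM in the deeper cluster's sub-cluster led by Mab21l4 and Crlf1, against 31.1 and 24.8 CPM in the others. That sub-cluster held 56.2% of the deeper cluster's control and 32.1% of its RMC-6236 cells. The part of this mix in the Adam12 ratio was not tested.

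Stress, metabolic and subtype lists differed by smaller amounts. All 24 immediate early and dissociation-stress genes were lower (median -0.40, -0.44 to -0.36, percentile 0.00), with Atf3 at 776 and 458 CPM (-0.76, or -0.08 as a mean of cells' CPM) and the chaperone Dnajb1 at 172 and 102 CPM (-0.76). Hypoxia and glycolysis genes had a median of -0.25 (percentile 0.03, 19 of 22 lower), with the glycolytic enzyme Pgk1 at 452 and 205 CPM (-1.14) and the angiogenic factor Vegfa at 197 and 108 CPM (-0.87). Oxidative phosphorylation genes stood at 0.18 (0.14 to 0.23, percentile 99.96, 19 of 22 higher) and unfolded protein response genes at -0.23 (percentile 0.20, 15 of 19 lower). Genes of the classical tumour subtype had a median of 0.30 (percentile 100, 17 of 24 higher), against summed CPM of 10197 and 6724 and -0.08 in thinned cells. In the deeper cluster, the sub-cluster led by Tff1 and Tff2 among others held most UMIs of this list, and its median was -0.14 (-0.36 to -0.015). That sub-cluster took 34.2% of the deeper cluster's control cells and 54.0% of its RMC-6236 cells. The other sub-clusters stood at 0.40 and 1.08. Basal-like subtype genes had a median of -0.38 (-0.46 to -0.29, percentile 0.01, 12 of 15 lower). NF-kB and cytokine genes had a median of -0.17 (percentile 0.26), with summed CPM of 1234 and 1696. Tumour lineage genes stood at -0.08 (percentile 19.5), with the surface protein Msln at 178 and 480 CPM (1.43, or 0.72 in thinned cells), autophagy and lysosome genes at -0.01, and p53 targets at -0.02. Myofibroblastic genes, a list made for fibroblasts, had a median of 0.51 in this class (0.25 to 0.70), against summed CPM of 1614 and 1360, with 0.55 in the deeper cluster alone and -0.27 there without its mesenchymal sub-cluster.

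S phase genes had a median of 0.13 (0.00 to 0.26, percentile 73.6) and G2 and M phase genes 0.13 (0.00 to 0.30, percentile 64.7), and in thinned cells -0.20 and -0.005. The proliferation gene Mki67 was 14.0 and 19.8 CPM (0.49, 0.08 to 0.94) and Top2a 19.2 and 20.8 CPM (0.10, -0.27 to 0.49; -0.67 in thinned cells). Acinar genes were higher for 16 of 16 members (1.13, 0.97 to 1.29, percentile 100). Acinar markers were also higher in other RMC-6236 cells, at 282 and 729 CPM in T cells and 383 and 744 CPM in macrophages.

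**Figure D2:**
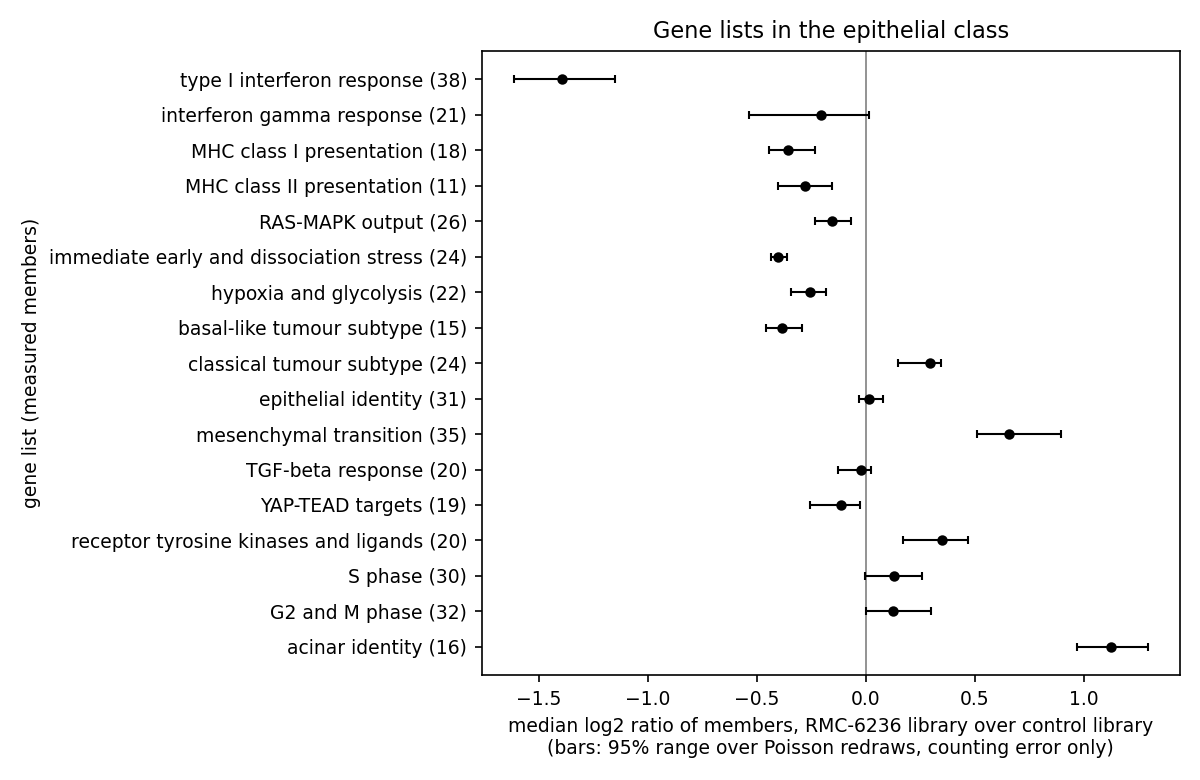
Median log2 ratio, RMC-6236 over control, of the measured members of 17 gene lists in epithelial cells, with bars for the 95% range over Poisson redraws of the counts. The type I interferon list stands at -1.39 and the mesenchymal transition list at 0.66, with RAS-MAPK output at -0.16 and epithelial identity at 0.01.

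After thinning to 1000 UMIs per cell, 303 control and 546 RMC-6236 epithelial cells remained, and 243 and 383 shallower ones were left out. Isg15 was then seen in 4.62% (2.55 to 7.63) of control and 1.10% (0.40 to 2.38) of RMC-6236 cells, against 10.99% and 3.55% unthinned. In B cells, with median depths of 2948 and 2652 UMIs against 1208.5 and 1306 in epithelial cells, thinned Isg15 shares were 1.52% and 1.09%, the latter close to the RMC-6236 epithelial share. B cells are not a class that lacks Isg15 or Ifit3, and the interferon-led cluster 12 is outside them. Their shares of these genes are therefore not a background level. Ifit3 was seen in 1.32% and 0.37% (2.38% and 0.97% unthinned), with 0.23% and 0 of 2114 in B cells, which allows up to 0.14% at 3 cells of the total, or 0.17% by Clopper-Pearson. Vim was seen in 30.03% (24.9 to 35.5) and 24.0% (20.5 to 27.8), or 34.6% and 33.5% unthinned, with 9.23% and 13.04% in acinar cells. Epcam was seen in 38.9% and 38.8% (36.4% and 37.6% unthinned; 0.95% and 1.57% in T cells) and Krt19 in 34.3% and 35.5% (38.8% and 41.1% unthinned; 0.32% and 2.46% in B cells). Dusp6 was seen in 6.60% and 6.23% (18.7% and 19.6% unthinned), Spry4 in 1.32% and 1.47% (8.06% and 6.997%) and Zeb1 in 5.61% and 5.68% (15.6% and 13.6%). In the comparison classes these were 0.69% and 0.43% for Dusp6 and 0.03% and 0.05% for Spry4 in B cells, and 2.63% and 2.87% for Zeb1 in macrophages. Mki67 (1.32% and 2.01%; 4.21% and 6.35% unthinned) and Top2a (1.65% and 1.47%; 5.49% and 5.17% unthinned) were not separable from neutrophils, at 1.10% and 2.32% and at 0.66% and 1.54%. H2-Aa was seen in 7.92% and 11.5% (18.9% and 17.4% unthinned; 4.62% and 5.80% in T cells), against its lower CPM, so no order is read from it. H2-K1 was seen in 21.5% and 15.6% (35.0% and 34.7% unthinned), below the 32.4% and 37.1% of neutrophils.

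In cluster 19, the deeper of the pair named fibroblast, interferon and antigen presentation genes were lower in the RMC-6236 library. Its name rests on 14 of 14 fibroblast markers, although none is among its 10 leading genes and the mesothelial marker Wt1 is. The cluster held 154 control and 412 RMC-6236 cells, with median depths of 15089 and 8458 UMIs. All 37 type I interferon genes were lower, with a median of -1.77 (-1.90 to -1.48, percentile 0.00), and interferon gamma genes had a median of -1.55 (-1.73 to -1.26, percentile 0.00, 18 of 22 lower), or -0.46 over 5 members in thinned cells. Isg15 was 456 and 54.2 CPM (-3.07, -3.28 to -2.87), Ifit3 98.2 and 6.83 CPM (-3.82), the antiviral enzyme Rsad2 118 UMIs against 1 (-6.87, -12.8 to -4.94) and the guanylate-binding protein Gbp6 29.9 and 2.59 CPM (-3.47, or -0.70 in thinned cells), with Slfn5 at -0.54. MHC class I genes (-0.93, 18 of 18 lower), MHC class II genes (-0.72, 9 of 9) and antigen-presenting fibroblast genes (-0.72, 13 of 13) were lower as well, with Cd74, the class II chaperone, at 545 and 235 CPM (-1.22, or -0.44 at resolution 2.0).

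The acute-phase gene Saa3 was 2981 and 108 CPM in this cluster (-4.79, -4.93 to -4.65), in 44 and 51 cells, or -3.58 with 4000 variable genes, and the chemokine Cxcl1 454 and 140 CPM (-1.70, -1.84 to -1.56), while the hyaluronan synthase Has1 was higher at 89.1 and 206 CPM (1.21, 1.01 to 1.42). The list of inflammatory fibroblast genes had a median of -0.07 (-0.33 to 0.11, percentile 33.1), with summed CPM of 9322 and 5453, and myofibroblastic genes 0.07 (-0.05 to 0.13, percentile 88.4). RAS-MAPK output stood at 0.08 (-0.03 to 0.21, percentile 69.2), with the pathway inhibitor Spred1 at 69.6 and 120 CPM (0.79, 0.55 to 1.03), and interferon ligands and receptors at -0.23 (percentile 6.93). S phase (-0.60) and G2 and M phase genes (-0.72) were lower, but 0.17 and 0.44 without the 10 top cells of each library, where the type I median was -1.13 and the interferon gamma median -0.94. By the naming rule, the highest ratios were those of Igfbp5 (2.71; 0.965 in thinned cells, with 61.8% of RMC-6236 UMIs in 2 cells), Fmo2 (2.46), Peg3 (2.41), Ctla2a at 357 and 1717 CPM (2.27, 2.17 to 2.36) and the hedgehog receptor Ptch1 at 24.7 and 109.5 CPM (2.14, 1.78 to 2.53). Serpinb2 (-3.77, 9 and 3 cells) and Rgs5 (-3.62, 12 and 9 cells) were among the lowest. Acinar markers in this cluster were 78.3 and 371 CPM, mesothelial markers 284 and 195 CPM (-0.54, -0.68 to -0.40), T cell markers 154 and 101 CPM and dendritic cell markers 172 and 142 CPM.

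The shallow fibroblast cluster 20 held 114 and 306 cells with 138925 and 358041 UMIs, and its ratios carry a shift of 0.24 with TMM and 0.28 with the median of ratios. Its 5 measured type I interferon genes had a median of -1.52 (-1.91 to -1.07), MHC class I genes -0.50 (-0.79 to 0.07), inflammatory genes -0.36 (-0.68 to 0.15), interferon ligands and receptors 0.29 (-0.76 to 1.04) and RAS-MAPK genes 0.00 (-0.56 to 0.65). Its myofibroblastic (-1.22), antigen-presenting (0.88) and MHC class II (0.67) medians turned direction with every barcode kept, with the stricter filter and at resolution 0.5, at values from -0.59 to 0.07. By the naming rule, Ccl21a, Apod, Pde3b, Ablim1 and Hivep2 had the highest ratios (3.71, 3.49, 2.72, 2.72 and 2.30) and Tpm2, Postn, Saa3, Eln and Mrpl52 the lowest (-2.40, -2.09, -2.06, -2.00 and -1.77), of which Pde3b, Ablim1, Eln and Mrpl52 turned with the stricter filter. Under that filter Apod stood at 1.39, Hivep2 at 0.65, Tpm2 at -0.26, Postn at -0.23, Saa3 at -4.78 and Ccl21a at 2.25. The ratio of 3.71 for Ccl21a rested on 1 and 50 UMIs, with 92.0% of the latter in 2 cells. The cluster's own fibroblast markers were 12100 and 6103 CPM, mural markers 799 and 260, acinar markers 936 and 2907, epithelial markers 266 and 771 and B cell markers 828 and 1170 CPM.

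Macrophages of the RMC-6236 library had lower interferon and MHC class II genes. All 39 type I interferon genes were lower (-0.63, -0.79 to -0.54, percentile 0.00), including the transcription factor Irf7 at 61.2 and 22.9 CPM (-1.42) and Ifit1 at 17.4 and 5.45 CPM (-1.67). The T cell attractant Cxcl10 was 120 and 45.7 CPM (-1.40), interferon gamma genes had a median of -0.21 (-0.31 to -0.09, 20 of 25 lower), MHC class I genes -0.26 (17 of 18 lower) and MHC class II genes -0.59 (-0.63 to -0.50, 10 of 11 lower), with summed class II CPM of 20720 and 15030. Markers of dendritic cells were 893 and 560 CPM in this class (-0.67, -0.73 to -0.62), and those of mast cells or basophils 9.7 and 84.4 CPM (3.11, 2.77 to 3.49). Ciita, the master regulator of class II genes, was 45.4 and 21.0 CPM (-1.11), whereas the lysosomal protease Ctss was 1803 and 2076 CPM (0.20). G2 and M phase genes had a median of -0.81 (-0.95 to -0.69, 32 of 32 lower) and S phase genes -0.45, which moved to -0.17 and 0.07 as means of cells' CPM, and G2 and M to -0.05 with 4000 variable genes and -0.19 in thinned cells. The unnamed cycling cluster 22 (78 and 124 cells) is outside every class.

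Inflammatory macrophage genes had a median of -0.37 (-0.46 to -0.25, 15 of 18 lower), with the nitric oxide synthase Nos2 at 42 UMIs against 5 (-2.86) and the cytokine Tnf higher at 67.6 and 89.8 CPM (0.41). Tissue-repair genes stood at 0.04 (12 of 22 higher; -0.002 at resolution 0.5), with summed CPM of 17521 and 22126, RAS-MAPK output at -0.22 (percentile 0.14), or 0.12 as a mean of cells' CPM, and interferon ligands and receptors at 0.05. The chitinase-like gene Chil3 was 1220 and 2389 CPM (0.97), Apoc4 19 and 83.7 CPM (2.13), Vcam1 27.9 and 76.8 CPM (1.46), Fbxo32 36.8 and 84.4 CPM (1.20) and Gpnmb 74.2 and 137 CPM (0.88). The lipoxygenase Alox15 was 150 and 28.5 CPM (-2.39), the fusion protein Dcstamp 341 and 87.6 CPM (-1.96, or -0.93 in thinned cells), Slc15a2 136 and 37.5 CPM (-1.85), Tnfrsf9 108 and 30.9 CPM (-1.80) and the elastase Mmp12 721 and 210 CPM (-1.78). Chil3 and Gpnmb are among the leading genes of macrophage cluster 9 (271 and 381 cells) and Dcstamp and Mmp12 of cluster 15 (347 and 371 cells), and the part of the mix of clusters in these ratios was not tested. The class median depth was 1487 and 3613 UMIs, and erythroid markers were 185 and 1.70 CPM.

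Neutrophils showed lower type I interferon genes in the RMC-6236 library, in 495 control and 282 RMC-6236 cells. All 36 type I interferon genes were lower (-0.88, -1.17 to -0.75, percentile 0.00), with Rsad2 at 133 and 13.7 CPM (-3.22, -4.26 to -2.44), and interferon gamma genes had a median of -0.55 (14 of 15 lower). Rsad2 stood at -1.59 with every barcode kept, -1.56 with each library clustered alone and -1.58 with 4000 variable genes, and thinned cells held 79 UMIs against 0. Chil3 was 219 and 2940 CPM (3.75, 3.57 to 3.93) in 40 and 155 cells, and the granule peptide Camp 1430 and 6815 CPM (2.25) in 17 and 24 cells, with 74.7% and 85.1% of their control UMIs in 2 cells each. Elane, the elastase of granulocyte precursors, was at 0 and 217 CPM, at least 95.8-fold higher, but in 2 cells, and Cstdc5 (3.46), Prtn3 (3.33) and Serpinb1a (3.08) followed. In these 3 genes 2 cells held 59.4%, 80.7% and 51.9% of the RMC-6236 UMIs, and as means of cells' CPM they stood at 2.15, 1.81 and 2.03. The alarmin Il1a was 913 and 333 CPM (-1.45), Siglecf, a leading gene of the cluster, 211 and 113 CPM (-0.89), Slc15a2 -2.40, P2ry14 -1.98, Gpr171 -1.93 and Cass4 -1.69. All 13 G2 and M phase genes were higher (1.48, 1.27 to 2.12), or 0.41 without the 10 top cells of each library, where S phase genes moved from 0.41 to -0.29.

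The neutrophil maturation list had a median of -0.11 (10 of 24 higher) but summed CPM of 66089 and 123986, and its direction turned in thinned cells (0.03). MHC class II genes stood at -0.53, or -1.29 without the 10 top cells, beside dendritic cell markers of 312 and 223 CPM. MHC class I genes stood at 0.11 (-0.14 to 0.21), or -0.39 as a mean of cells' CPM, RAS-MAPK output at 0.02 (-0.47 to 0.15), or -0.63 in thinned cells, and interferon ligands and receptors at 0.06. Markers of macrophages (1959 and 5915 CPM), epithelial cells (1171 and 3697 CPM) and neutrophils (47130 and 95170 CPM) were all higher in this class. The macrophage markers include Chil3, which was higher here, and the epithelial ones Lcn2, which is also on the neutrophil maturation list. RNA of other cells is therefore not read from these sums. Other scalings shift its ratios by 0.10 (TMM) and 0.10 (median of ratios).

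T cells of the RMC-6236 library had lower type I interferon genes and higher interferon gamma response genes. Type I genes had a median of -0.80 (-0.92 to -0.62, percentile 0.00, 37 of 39 lower), with Ifit3 at 13.5 and 1.93 CPM (-2.75, -3.78 to -1.96), the interferon-induced Ifi27l2a at 926 and 336 CPM (-1.46) and Rnf213 at 243 and 112 CPM (-1.11). Interferon gamma genes had a median of 0.30 (0.19 to 0.35, percentile 100, 20 of 24 higher), while Stat1, which serves both pathways, was 306 and 323 CPM (0.08) and Gbp9 stood at -0.55. Ifng itself was 6.13 and 12.7 CPM (1.06, 1.73 in thinned cells) in 42 and 24 cells. The chaperone genes Hspa1a, at 750 and 151 CPM (-2.31, -2.41 to -2.22), and Hspa1b, at 1072 and 239 CPM (-2.16), had the lowest ratios among genes of at least 50 CPM that meet the naming rule, and Ly6c2 stood at -1.003. Elovl6 (0.91), the transcription factor Irf4 (0.89), Gadd45b (0.87), Maf (0.82) and Kdm6a (0.72) had the highest. Hspa1a and Hspa1b are on the list of immediate early and dissociation-stress genes, which was not summarised in T cells.

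Naive and memory T cell genes had a median of -0.19 (-0.22 to -0.13, 8 of 10 lower), with the quiescence factor Klf2 at 901 and 463 CPM (-0.96) and the chromatin organiser Satb1 at 1618 and 2026 CPM (0.32). Klf2 is also on the list of immediate early and dissociation-stress genes, so no loss of quiescence is read from its value. Tcf7 and Lef1 of this list are leading genes of cluster 2, which held 1413 of 3255 control and 593 of 1683 RMC-6236 T cells. The Cd8-led cluster 4 held 970 and 409 cells and the Foxp3-led cluster 14 held 471 and 354. The part of this mix of clusters in the T cell ratios was not tested. Regulatory T cell genes stood at 0.10 (percentile 96.9) with Foxp3 at -0.08 (-0.38 to 0.20), checkpoint genes at 0.10, S phase at 0.09, G2 and M phase at 0.20 (-0.05 to 0.41) with summed CPM of 715 and 618, MHC class I genes at -0.03, interferon ligands and receptors at -0.06, and RAS-MAPK output at 0.13 (0.00 to 0.32), or -0.04 after subtraction of free RNA. Cytotoxicity genes (-0.25) and MHC class II genes (0.53) turned direction under 5 and 4 alternatives, among them the common Scrublet threshold (0.29 and -0.84). Markers of epithelial cells (81.1 and 211 CPM), fibroblasts (69.5 and 156 CPM) and B cells (263 and 322 CPM) were higher among RMC-6236 T cells.

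**Figure D3:**
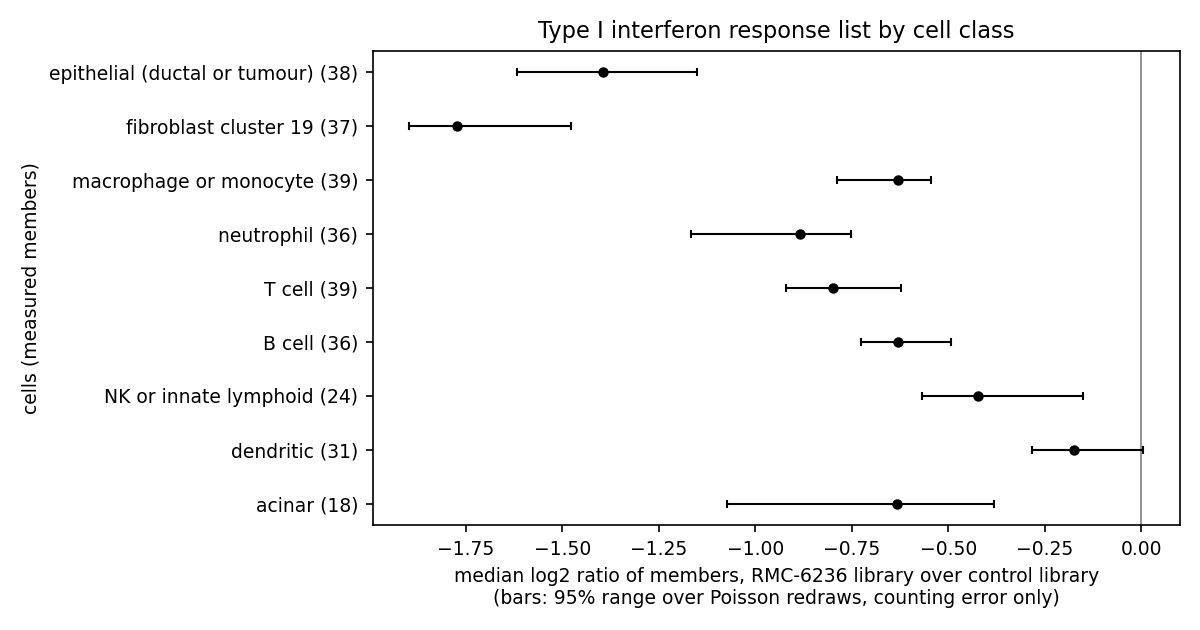
Median log2 ratio, RMC-6236 over control, of the measured type I interferon response genes in 9 cell classes or clusters, with bars for the 95% range over Poisson redraws. Every median lies below 0, from -1.77 in fibroblast cluster 19 and -1.39 in epithelial cells to -0.18 in dendritic cells, whose bar reaches 0.01.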

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

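These contrasts between cell classes were picked out by a fixed rule, and the alternatives quoted for them that leave out cells or use a common Scrublet threshold were chosen after the result was seen. In each, a list median lay on one side of 0 in some classes and on the other side in others, and the difference was not tested, since each group is 1 library.

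Interferon gamma response genes were lower in the RMC-6236 library in fibroblast cluster 19 (-1.55, percentile 0.00), neutrophils (-0.55, percentile 0.56) and macrophages (-0.21, percentile 0.32), and higher in T cells (0.30, percentile 100). MHC class II genes were lower in fibroblast cluster 19 (-0.72), macrophages (-0.59) and epithelial cells (-0.28), and higher in T cells (0.53). Of these, 4 alternatives turned the T cell value, and the epithelial value was 0.45 in thinned cells and 0.48 without the 10 cells of each library with the most UMIs of the list. G2 and M phase genes were lower in macrophages (-0.81, or -0.05 with 4000 variable genes) and fibroblast cluster 19 (-0.72), and higher in neutrophils (1.48). Without the 10 cells of each library with the most UMIs of the list, the value of cluster 19 was 0.44 and that of neutrophils 0.41. Myofibroblastic genes were lower in fibroblast cluster 20 (-1.22) and higher in epithelial cells (0.51), and antigen-presenting fibroblast genes were lower in fibroblast cluster 19 (-0.72) and higher in cluster 20 (0.88). Both values of cluster 20 turned direction under 3 alternatives, which change the cells that the cluster holds. The epithelial myofibroblastic value was -0.06 at resolution 2.0, -0.045 in thinned cells and -0.27 in the deeper cluster without its mesenchymal sub-cluster.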

How the results depend on the processing

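The settings that leave out cells or sub-clusters, keep the deep epithelial cluster alone or use a common Scrublet threshold were chosen after the result was seen. No paired analysis was possible because each group has 1 library. Of 625 values of epithelial lists under alternatives, 513 stayed within the main interval, 97 moved beyond it, with the same direction or about a main value whose interval held 0, and 15 reversed. For lists in other classes these were 611, 106 and 27 of 744, for epithelial genes 796, 193 and 13 of 1002, for genes in other classes 882, 146 and 8 of 1036, for class shares 60, 21 and 1 of 82, and for thinned shares 33, 3 and 0 of 36. The epithelial type I interferon median stayed negative throughout, from -1.75 to -0.32, and the share ratio of the pooled fibroblast clusters positive, from 1.62 to 1.90. Depth limits the shallow clusters most, where few list members are measured, and rare transcripts such as Ifit3. The cause was not tested for any value that follows. All are log2 ratios or list medians.

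With every barcode kept, share ratios were 0.86 for epithelial cells, 1.62 for fibroblasts, -0.57 for B cells, -0.77 for T cells and 0.10 for macrophages. Neutrophil type I interferon was -0.61 and T cell cytotoxicity 0.26, and in cluster 20 MHC class II was -0.36, myofibroblastic 0.013, antigen-presenting -0.37, Ablim1 -0.14 and Eln 0.10. With the stricter filter, share ratios were -0.22 for B cells, -0.44 for T cells and 0.59 for macrophages, and the epithelial mesenchymal median 0.49. In cluster 20 MHC class II was -0.46, myofibroblastic 0.073, antigen-presenting -0.59, Pde3b -0.04, Ablim1 -0.17, Eln 0.16 and Mrpl52 0.015. With each library clustered alone, share ratios were 0.25 for epithelial cells, 1.63 for fibroblasts, -0.40 for B cells and -0.022 for macrophages. Epithelial RAS-MAPK output was -0.066, identity 0.082 and tissue-repair -0.049, type I interferon -0.54 in macrophages and -0.66 in neutrophils, and in T cells MHC class II -0.069 and cytotoxicity 0.26.

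At Leiden resolution 0.5 the macrophage share ratio was 0.44, macrophage tissue-repair -0.002, and in cluster 20 MHC class II -0.40, myofibroblastic 0.027, antigen-presenting -0.52, Ablim1 -0.14 and Eln 0.12. At 2.0, epithelial RAS-MAPK output was -0.25, type I interferon -1.03, identity 0.13, myofibroblastic -0.06 and Zeb1 -0.021. With 4000 variable genes, neutrophil type I interferon was -0.66, and in T cells MHC class II was -0.044 and cytotoxicity 0.27. With Scrublet calls kept, T cell MHC class II was -0.67. With the common threshold it was -0.84 and T cell cytotoxicity 0.29.

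In thinned cells, epithelial type I interferon was -0.32, interferon gamma 1.70, MHC class II 0.45, nucleic acid sensing 0.40, G2 and M phase -0.005, classical subtype -0.084, myofibroblastic -0.045, macrophage inflammatory 0.33, tissue-repair -0.12, Dusp6 -0.11, H2-Aa 0.23 and Egr1 0.001. Type I interferon was -1.39 in cluster 19 and -0.61 in T cells, neutrophil maturation 0.029 and T cell cytotoxicity 0.002. As means of cells' CPM, epithelial RAS-MAPK output was -0.25, type I interferon -1.12, identity 0.14, Dusp6 -0.064, H2-K1 0.14 and Zeb1 -0.003, cluster 19 type I interferon -1.42, macrophage RAS-MAPK output 0.12 and S phase 0.066, and neutrophil maturation 0.045. With free RNA subtracted, epithelial type I interferon was -1.75, interferon gamma 0.028 and naive T cell genes 0.21, and T cell RAS-MAPK output -0.037. With the median of ratios, epithelial identity was -0.034, and with 5 counts added neutrophil type I interferon was -0.74.

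In the deep epithelial cluster alone, interferon gamma was -0.68 and mesenchymal transition 0.745. Without its mesenchymal sub-cluster, type I interferon was -0.98, identity 0.14, mesenchymal transition -0.071, receptor tyrosine kinases -0.024, myofibroblastic -0.27 and Zeb1 -0.52. Without the 10 cells with the most UMIs of a list, epithelial type I interferon was -1.09, MHC class II 0.48, identity 0.15, mesenchymal transition 1.22 and macrophage inflammatory 0.29. In cluster 19 type I interferon was then -1.13, S phase 0.17 and G2 and M phase 0.44, and neutrophil maturation 0.014. Without the 2 cells with the most UMIs of a gene, Gcg was -0.69 with no UMI left in either library, Ins2 -0.40, Psca 0.13, Tff1 0.42 and H2-Aa 0.031.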

Other observations

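The tests of fibroblast RNA below were chosen only after the result was seen, as were the alternatives that leave out cells. The deep epithelial cluster split into 3 sub-clusters. The sub-cluster led by Mab21l4, Crlf1 and Cldn6 held 56.2% (47.7 to 64.4) of its control cells and 32.1% (26.5 to 38.1) of its RMC-6236 cells, and that led by the mucosal genes Pigr, Gkn3, Tff1, Tff2 and Muc6 held 34.2% (26.6 to 42.5) and 54.0% (47.8 to 60.1). The mesenchymal one, led by Prrx1, Cdh11, Mmp2 and Col1a2, held 14 cells (9.59%, 5.34 to 15.6) and 37 cells (14.0%, 10.0 to 18.7). Over both libraries the mesenchymal one had 26.9 CPM of Epcam, against 1477 and 1497 CPM in the others, and 1936 CPM of the cell cycle inhibitor gene Cdkn2a, chosen after its values were seen, against 679 and 287 CPM. Its type I interferon median stood far below the others, at -4.50 (-5.13 to -3.76), with MHC class I at -2.01 (-2.45 to -1.60), against 0.006 and -0.34 in the others. Col1a2 had 3 control and 882 RMC-6236 UMIs in the deep cluster, and 2 and 28 without the mesenchymal sub-cluster. Nearly all Col1a2 UMIs of that sub-cluster thus came from RMC-6236 cells, so its medians may compare unlike cells. A median control cell of the mesenchymal sub-cluster gave 2409 CPM of the interferon list and a median RMC-6236 cell 357 CPM, although 3 cells held 67.2% of the control UMIs. In the other sub-clusters these medians were 335 and 235 CPM, and 776 and 353 CPM. RAS-MAPK output was near 0 in each sub-cluster (0.03, -0.04 and -0.04). A finer split at resolution 0.5 held a sub-cluster of 15 control and 33 RMC-6236 cells with immune genes in the lead. Its leading genes included the B cell markers Pax5, Cd79a and Bank1 and the MHC class II gene H2-Ob, beside 1045 CPM of Epcam. Such cells, with epithelial and immune RNA together, are part of the epithelial MHC class II and other immune list values.

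Type I interferon genes were also lower in classes outside the main comparisons, all named here after their values were seen. The median was -0.63 (-0.72 to -0.49) in B cells, from which the unnamed interferon-led cluster 12 (123 and 12 cells) is left out, -0.63 (-1.07 to -0.38) in acinar cells and -0.42 (-0.57 to -0.15) in natural killer cells. In dendritic cells it was -0.18 (-0.28 to 0.01), with 0.04 in cluster 6, led by Clec9a, and -0.35 in cluster 11, led by Ccl22 and Fscn1. Interferon gamma genes in B cells stood at 0.28 (0.14 to 0.38), on the same side of 0 as in T cells.

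The lower type I interferon list in RMC-6236 epithelial cells was weighed against technical explanations. RNA from other cells was sized by B and T cell markers alone (3.54% and 3.28% of the class) and given the mean profile of all cells outside the class. At that size and profile it could supply at most 16.4% (15.1 to 17.6) of the drop in the list's CPM. This argues against RNA traced by these markers as the main source. It sets no limit for RNA of cells that they do not trace, such as macrophages, dendritic cells or fibroblasts. A changed mix of sub-clusters is argued against as the whole cause, since the list was lower within each of the 3, with a middle value of -1.16 (-1.29 to -0.89) and a highest of -0.76 (-1.08 to -0.37), although a finer split at resolution 1.0 held a sub-cluster at -0.25. Handling of the libraries and the treatment cannot be told apart with 1 library per group, and this stays open because the list was lower in nearly every class. An effect of RMC-6236 stays open as well and was not tested.

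The higher mesenchymal list in RMC-6236 epithelial cells has several open explanations. In the deep cluster, fibroblast markers outside the list were higher by only 21.6% (17.8 to 25.9) of what fibroblast RNA would need for the collagen values of 16.7 and 424 CPM, which argues against that source there. In the shallow cluster this was 32.9% (12 to 58.5), too wide to decide, so fibroblast RNA cannot be told apart there. More cells of the mesenchymal sub-cluster may account for the median, which was 0.745 in the deep cluster alone and -0.071 (-0.28 to 0.15) without that sub-cluster. The list members Prrx1, Cdh11, Mmp2 and Col1a2 are among that sub-cluster's leading genes, and it was picked by its Prrx1 level. A lower median without it was therefore largely set in advance and does not decide the question. The intervals of the sub-cluster's share of cells overlap, so its 14 control and 37 RMC-6236 cells do not settle whether that share was larger. Against a larger share as the whole account, the list stood at 0.37 (0.24 to 0.50) within the sub-cluster. Leaving out the 10 cells of each library with the most UMIs of the list moved the class median to 1.22. This removal cannot weigh a larger share, since it picks cells by the list itself. An equal number was also taken from unequal sets, as the sub-cluster held 14 control and 37 RMC-6236 cells. A higher level per cell and a larger share of such cells both stay open, untested against treatment.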
